A study of Mus musculus with 9 samples.

How the data were processed

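RNA was sequenced in 6 libraries and H3K4me3 chromatin immunoprecipitation in 3 libraries, all from cells sorted from the pooled bone marrow of untreated Balb/c mice. Granulocyte-macrophage progenitors (GMP), eosinophil progenitors (EoP) and mature eosinophils (Eos) each gave 2 RNA libraries and 1 H3K4me3 library. Per the labels, GMP were lineage-negative cells with CD34, high c-kit and the Fc gamma receptors, EoP were lineage-negative cells with CD34, low c-kit and CD125, and Eos were cells with Siglec-F and CCR3. Each library was put in its group by its title. The series' design text gives the 2 RNA libraries of a cell type as separate sorts. Neither it nor the labels say that the sorts used different animals, so the p-values measure the spread between these samples.

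The authors' RNA files list, per RefSeq transcript, an estimated count rounded to whole numbers and an RPKM value; the tool that made the deposited estimated counts is not given in the sources used here. STAR 2.4.0c, Bowtie 1.0.0 and the build mm10 are named in the submitters' processing notes, which give no role for either tool. The 31213 lines of each file held 30396 different transcripts, of which 29848 matched a RefSeq table used to match gene list symbols to the files. Relative transcript lengths were taken as the ratio of deposited count to RPKM. Counts were summed over all lines of each gene symbol to 23471 genes, of which 22 had transcripts on several chromosomes. A transcript listed on several lines was added once per line. The deposited RPKM values of the authors were summed the same way and used for an alternative test and for levels beside promoter peaks.

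The H3K4me3 files are the authors' peak lists, 1 per library, with replicates not pooled. Per the file headers they give each summit's pileup signal, its −log10 p and q, its fold enrichment and the length of the peak; the caller and any control library are not given in the sources used here. The score, fold and length of a peak are the authors' own and were used only within their list. Read depth of these libraries is unknown. Coordinates are 1-based on mm10, the build per the submitters' processing notes. A gene had a promoter peak where the authors' file annotated a peak to its promoter, which covered peaks within 1000 bases of the start. The alternatives were the 19816 top-ranked peaks of each list, a −log10 q of at least 8.23, and any peak within 1000 or 3000 bases of a start. Peaks of different lists counted as shared when they overlapped by at least 1 base, with at least 50% of the shorter or of both peaks as alternatives.

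Gene counts were tested in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16 after its default expression filter, with TMM factors and 1 fit of the 6 libraries with cell type as the only term, which left 3 residual degrees of freedom. The filter kept 14324 genes. The common dispersion was 0.0692 and the prior degrees of freedom 7.00. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, with no minimum fold. Fold changes are log2 values with the standard error of the fit. For a gene with no count in 1 of the groups, the fold is given as a lower bound against a floor of 3 counts over that group, and with 1 to 3 counts as a ratio of normalised totals with a 95% counting interval. Intervals and floors cover counting error only.

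The tests, the 35 gene lists, the rule for naming genes and the main alternatives were set before the data were examined. Of the lists, 34 had at least 5 members in the test; mitochondrial transcripts were not analysed here. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over lists within a comparison, and again with an estimated correlation. At the preset correlation, 14 lists were called for EoP against GMP, 20 for Eos against EoP and 22 for Eos against GMP; with an estimated correlation the numbers were 0, 0 and 0, so every list p has that limit. The genes named are the 6 largest rises and falls at each step (3 for Eos against GMP) at a mean of at least 20 CPM in the higher group with libraries that did not overlap, up to 4 called members of a list by size, the sort gate genes, each called eosinophil lineage transcription factor, the 6 genes with the largest smaller change in each class over both steps, and for each pair of cell types 4 genes by fold enrichment of a peak listed in 1 of them. Gene models, micro and small nucleolar RNAs and receptor segments were left out of the rule's largest changes. A gene that the rule names is not reported here.

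The alternatives were DESeq2 size factors, upper quartile factors and library size alone, the DESeq2 1.42.0 Wald test, limma-voom, no filter, at least 50 counts in 2 libraries, the replicate number as a block, limma on log2(RPKM + 0.5) over genes of at least 1 RPKM in 2 libraries, only the compared groups, a minimum change of 2-fold, and each library left out in turn. On counts simulated from these libraries over 12793 genes, the test of Eos against EoP called 7 unchanged genes among 110 calls and recovered 9.84% of 61 genes changed 2-fold, 61.7% of 60 changed 4-fold and 96.8% of 62 changed 16-fold. For Eos against GMP it called 13 unchanged genes among 117 calls, and for EoP against GMP, in which no gene was changed, 2 genes.

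Estimated totals ran from 5226653 to 12088134 per library, so that 3 counts stood for 0.248 to 0.574 CPM. The 45S ribosomal RNA precursor gene Rn45s took 7.48% to 12.9% of the counts. Within a cell type the libraries differed by more than sampling noise, with a chi-square per degree of freedom of 9.49 in GMP, 29.6 in EoP and 52.1 in Eos over genes of at least 10 counts, so no library was a copy of another. Genes with identical or shared sequence could not be told apart by these counts: Ear3 and Ear12, Hbb-b2 and Hbb-bt, Hbb-b1 and Hbb-bs, and Hba-a1 and Hba-a2 held identical counts, and the split between the other Ear genes is uncertain.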

Results

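GMP, EoP and Eos from bone marrow were compared by RNA sequencing (2 libraries each) and by H3K4me3 peaks (1 library each). In EoP the 11 eosinophil granule genes together held 255694 and 203872 CPM. These CPM are scaled by TMM factors and are not shares of all counts, and reads shared between Ear genes can enter the sum more than once. Prg2, for major basic protein, took 15.5% and 13.2% of all counts in the EoP libraries, 0.123% and 0.0302% in GMP and 0.403% and 0.263% in Eos. Epx, for eosinophil peroxidase, had a mean of 92.9 ± 67.5 CPM (SD, n = 2) in GMP, 25094 ± 2653 in EoP and 325 ± 157 in Eos. The Pearson correlation of log2 CPM between libraries of a cell type was 0.966 in GMP, 0.974 in EoP and 0.967 in Eos. The GMP libraries were the shallowest, at 6576661 and 5226653 counts, against 9628492 and 12088134 in EoP and 10940000 and 10790618 in Eos.

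Il5ra, Siglec5 and Ccr3 rose from GMP to EoP, and Kit, used to part these gates, did not pass between them. Il5ra, which encodes CD125, rose 208-fold from GMP to EoP, from a mean of 1.98 ± 0.276 to 418 ± 26.3 CPM (SD, n = 2; log2 fold change 7.70, SE 0.43), with both EoP libraries above both GMP libraries (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 2.31e-05). Siglec5, the RefSeq name of the mouse gene for Siglec-F, rose by 3.99 log2 units (SE 0.26) and reached 272 ± 13.6 CPM in EoP, which were not sorted on Siglec-F. It did not pass between EoP and Eos (log2 fold change 0.41, adjusted p = 0.185). Ccr3 rose by 4.46 (SE 0.42) to 27.9 ± 9.33 CPM in EoP and by a further 6.55 (SE 0.40) to 2623 ± 495 CPM in Eos, with no overlap between libraries at either step (edgeR, Benjamini-Hochberg adjusted p = 0.000163 and 1.22e-05). Kit did not pass in EoP against GMP, although EoP were gated on low c-kit (log2 fold change −0.47, SE 0.39, adjusted p = 0.409). It fell by 1.54 (SE 0.40) from EoP to Eos, a call that was lost without EoP replicate 2 (log2 fold change −1.38, adjusted p = 0.0588). Cd34 fell by 1.14 (SE 0.33) from GMP to EoP, but the call was lost whenever any GMP or EoP library was left out (adjusted p from 0.128 to 0.168). From EoP to Eos it fell by 2.13 (SE 0.35), with both Eos libraries below both EoP libraries (edgeR, Benjamini-Hochberg adjusted p = 0.0016). The Fc gamma receptor genes, in the GMP gate, were higher in EoP than in GMP, Fcgr3 by 2.75 (SE 0.27) and Fcgr2b by 1.76 (SE 0.28), the latter lost without GMP replicate 1 (1.66, adjusted p = 0.0519). From EoP to Eos, Fcgr3 rose by 1.28 (SE 0.26) and Fcgr2b did not pass (0.64, adjusted p = 0.0893). Il5ra rose by 1.11 (SE 0.31), a call lost without EoP replicate 1, EoP replicate 2 or Eos replicate 2 (adjusted p = 0.0835, 0.106 and 0.0628). Of the 7 sort gate genes tested, 5 rose and 1 fell from GMP to EoP (camera adjusted p = 2.10e-09; adjusted p = 0.238 with an estimated correlation), and 3 rose and 2 fell from EoP to Eos (camera adjusted p = 0.176).

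**Figure D1:**
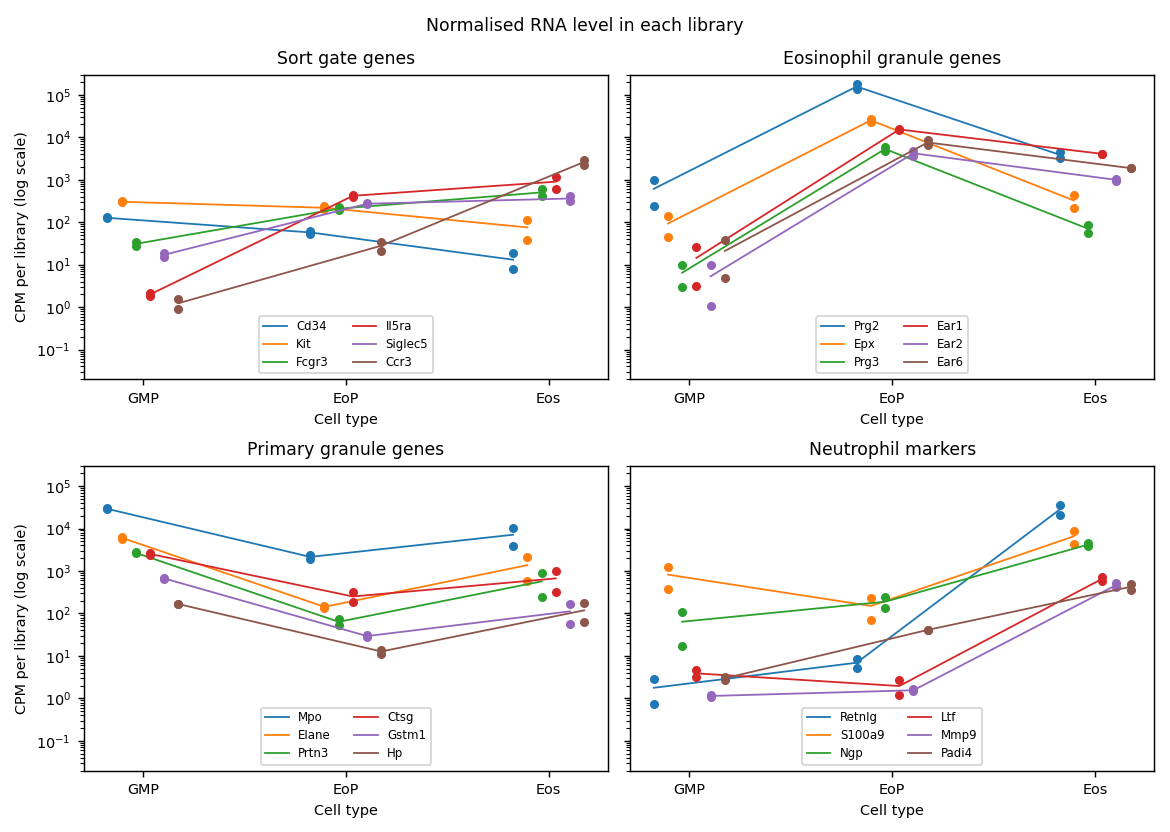
Normalised RNA level (CPM, log scale) of named genes in GMP, EoP and Eos, with 1 point per library and lines through the means. Panels hold sort gate genes, eosinophil granule genes, primary granule genes and neutrophil markers.

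Most eosinophil granule genes were higher in EoP than in GMP. Most genes of the GMP primary granule list and 12 of 24 monocyte, macrophage and dendritic cell genes were lower. Prg3 rose 806-fold (log2 fold change 9.65, SE 0.64), Epx 270-fold (8.08, SE 0.75) and Prg2 257-fold (8.01, SE 0.94), all encoding granule proteins, with 2 of 2 EoP libraries above both GMP libraries (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 3.18e-05, 0.000144 and 0.000523). Ear1, an eosinophil ribonuclease gene, rose 1048-fold (10.03, SE 0.96), Ear3 and Ear12, with identical counts, by 10 (SE 0.85) and Ear2 by 9.59 (SE 0.84). In the opposite direction Elane, for neutrophil elastase, was 42.5-fold lower in EoP (log2 fold change −5.41, SE 0.60), Prtn3 42.2-fold lower (−5.40, SE 0.59) and Mpo 13.5-fold lower (−3.76, SE 0.56), with both EoP libraries below both GMP libraries (edgeR, Benjamini-Hochberg adjusted p = 0.00039, 0.000349 and 0.00206). Of 11 granule genes 10 rose and 0 fell, 11 and 0 when adjusted over the list alone (camera adjusted p = 2.28e-26; adjusted p = 0.342 with an estimated correlation). Of 11 genes of the GMP primary granule list 1 rose and 8 fell (camera adjusted p = 2.31e-06, and 0.465 with an estimated correlation). They are called primary granule genes here, though not all of them, such as Igsf6, encode granule proteins. Prg2 was uneven in GMP, at 983 and 235 CPM.

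Under the naming rule, a gene that fell had a mean of at least 20 CPM in GMP and libraries that did not overlap. Its largest falls outside the granule genes were in Muc4 (log2 fold change −5.70, SE 0.55), the T cell and natural killer gene Gzmb (−5.62, SE 0.86), the stem cell surface gene Prom1 (−5.55, SE 0.51) and Nav2 (−5.15, SE 0.51). All were lower in both EoP libraries (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.000187, 0.00229, 0.000136 and 0.000211). The Y-linked genes Eif2s3y and Ddx3y, with no count in GMP, were at least 187-fold and 185-fold higher in EoP, a difference that the sex of the pooled mice, not given, may set. Of 27 stem and progenitor genes 1 rose and 8 fell, 1 and 12 when adjusted over the list alone. The number that fell was 3, 2, 4 and 4 with each GMP or EoP library left out and 14 without either Eos library (camera adjusted p = 0.0304; adjusted p = 0.509 with an estimated correlation). The list call was lost without EoP replicate 1 (camera adjusted p = 0.156). Cd27 fell by 3.56 (SE 0.52). Of 23 neutrophil markers 3 rose and 8 fell, 4 and 10 over the list alone (camera adjusted p = 0.512), and the 8 became 4 and 5 without GMP replicates 1 and 2 and 5 without EoP replicate 2. Csf3r, for the receptor of granulocyte growth factor, fell by 4.40 (SE 0.33) and Fcnb by 3.09 (SE 0.54). Padi4 rose by 3.77 (SE 0.28) and Cybb by 2.73 (SE 0.33). Of 24 monocyte, macrophage and dendritic cell genes 3 rose and 12 fell, 3 and 13 over the list alone and 8 without GMP replicate 2 (camera adjusted p = 0.000424; adjusted p = 0.509 with an estimated correlation). Ly6c2 (−4.68, SE 0.35) and F13a1 (−4.14, SE 0.36) fell, and Emr1, which encodes F4/80, rose by 5.28 (SE 0.41).

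Transcription factors of the eosinophil lineage rose more often than they fell. Of 25 tested, 11 rose and 4 fell, 12 and 4 when adjusted over the list alone. Without GMP replicate 1 the numbers were 7 and 1, and the number that fell was 1 without GMP replicate 2 and 2 without either EoP library (camera adjusted p = 0.00012; adjusted p = 0.344 with an estimated correlation). Ikzf3 rose 68.7-fold (log2 fold change 6.10, SE 0.38) and Gata1 13.6-fold (3.76, SE 0.29), each in both EoP libraries (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 2.36e-05 and 5.72e-05). Gfi1b rose by 3.40 (SE 0.73), Id2 by 3.08 (SE 0.30), Bhlhe40 by 2.83 (SE 0.62), Cebpe, needed for granule formation, by 2.76 (SE 0.31) and Ikzf2 by 2.17 (SE 0.27). Irf8, a monocyte and dendritic cell regulator, fell by 3.27 (SE 0.56), again in both libraries (edgeR, Benjamini-Hochberg adjusted p = 0.00404). The remaining calls were each lost in fits with a library left out, which had fewer samples. In those fits the log2 fold changes were 1.47 to 2.17 for Zfpm1, 1.16 to 1.92 for Id1, 1.11 to 1.56 for Ets1 and 0.81 to 1.39 for Ikzf1. They were −1.03 to −1.74 for Cebpa, −1.10 to −1.44 for Nfix and −1.09 to −1.35 for Nfia. Zfpm1 rose by 2.26 (SE 0.61), lost without GMP replicate 1 (adjusted p = 0.0985) or EoP replicate 1 (0.0801). Id1 rose by 1.76 (SE 0.43), lost in 3 fits (adjusted p from 0.0904 to 0.136), Ets1 by 1.33 (SE 0.30), lost in 3 (0.0578 to 0.0901), and Ikzf1 by 1.00 (SE 0.27), lost in 4 (0.0587 to 0.203). Cebpa fell by 1.59 (SE 0.42), lost in 3 (0.0949 to 0.163), Nfix by 1.35 (SE 0.32), lost in 4 (0.0668 to 0.122), and Nfia by 1.30 (SE 0.38), lost in 4 (0.110 to 0.162). Gata2 (0.01), Sfpi1, which encodes PU.1 (0.35), Xbp1 (0.49), Stat5b (0.27) and Runx1 (−0.16) did not pass.

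Among other lists, eosinophil surface receptor and adhesion genes had 9 rises and 1 fall of 26, 5 rises without GMP replicate 1 and 6 without GMP replicate 2 (camera adjusted p = 2.31e-06; adjusted p = 0.465 with an estimated correlation). Lipid mediator genes had 5 rises and 1 fall of 12, 6 and 1 over the list alone, and at the lowest 3 rises with a library left out (camera adjusted p = 0.000852; adjusted p = 0.342 with an estimated correlation). Alox15 rose 256-fold (log2 fold change 8.0, SE 0.50, both EoP libraries; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 2.36e-05), Tbxas1 by 2.72 (SE 0.37) and Alox5 by 2.27 (SE 0.31). Endoplasmic reticulum protein folding genes had 10 rises and 0 falls of 26, 12 and 0 over the list alone. There were 2, 1 and 2 rises without GMP replicate 1, GMP replicate 2 or EoP replicate 1 and 19 without either Eos library (camera adjusted p = 0.000281; adjusted p = 0.675 with an estimated correlation). Creld2 rose by 2.09 (SE 0.32) and Ddit3 by 2.5 (SE 0.70). The Ddit3 call was lost in 3 fits with a library left out, where its log2 fold change ran from 0.74 to 2.78. Cell cycle inhibitors had 7 rises and 0 falls of 14, 9 and 0 over the list alone. The rises were 1 without GMP replicate 1, 4 without GMP replicate 2 and 4 without EoP replicate 1 (camera adjusted p = 0.000402; adjusted p = 0.465 with an estimated correlation). Gadd45a rose by 2.81 (SE 0.66) and Ccng2 by 1.92 (SE 0.38). The Gadd45a call was lost in 3 fits with a library left out, at log2 fold changes from 1.28 to 3.54. The Ccng2 call was lost without GMP replicate 1, at 1.84. Replication genes had 2 rises and 0 falls of 33 (0 and 0 over the list alone; camera adjusted p = 0.326), and mitosis genes 2 and 0 of 28 (1 and 0; camera adjusted p = 0.00590; adjusted p = 0.863 with an estimated correlation). With any GMP or EoP library left out replication genes had 0 or 1 rises and mitosis genes 0 or 1, and without either Eos library 5 and 13. Interferon-response genes had 2 rises and 10 falls of 23, 4 and 11 over the list alone, and 6 or 7 falls with any GMP or EoP library left out (camera adjusted p = 0.0316; adjusted p = 0.505 with an estimated correlation). The call was lost without EoP replicate 1 or 2 (camera adjusted p = 0.0744 and 0.0638). Oasl2 fell by 3.03 (SE 0.60) and Ifi44 by 3.02 (SE 0.48).

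Lists for several other cell types and general functions were not called at this step. Mast cell and basophil genes had 3 rises and 2 falls of 13 (4 and 3 over the list alone; camera adjusted p = 0.107), with Il4 up by 3.81 (SE 0.41). The basophil genes Prss34 and Mcpt8 were uneven within EoP, at 282 and 1782 CPM and at 141 and 806 CPM. Megakaryocyte genes had 2 rises and 1 fall of 11 (0.223), with Itga2b up by 3.32 (SE 0.30; camera adjusted p in brackets). Erythroid genes had 0 and 1 of 19 (0.326), B cell genes 1 and 1 of 15 (0.904), T and natural killer cell genes 0 and 5 of 15 (0.107), and stromal genes 2 and 3 of 12 (0.648). With each GMP or EoP library left out the falls of T and natural killer cell genes were 0, 1, 1 and 2 and the stromal falls 0 in each fit, and the mast cell and basophil rises ran from 1 to 7. Ribosomal protein genes had 1 rise and 1 fall of 79 (0.614), ribosome biogenesis genes 0 and 6 of 30 (0.137) and oxidative phosphorylation genes 1 and 1 of 77 (0.886), each 0 and 0 over the list alone. With any GMP or EoP library left out their falls were 0, and without either Eos library they were 9, 13 and 9. Pattern recognition genes had 4 rises and 9 falls of 26 (4 and 12 over the list alone; 0.276), and the falls ranged between 2 and 12 with a library left out. Tlr5 had no count in EoP and was at least 10.3-fold lower, a call lost whenever any GMP or EoP library was left out (adjusted p from 0.0528 to 0.102). Cytokine and chemokine genes had 3 and 3 of 25 (0.989). Ccl6 rose by 4.97 (SE 0.44) and Tnfsf13 fell by 5.09 (SE 0.59). No gene of 19 in the activation and dissociation stress list passed in edgeR (0.648), but 10 fell without EoP replicate 1 and 6 rose without EoP replicate 2. The list differed between the EoP libraries, with Fos at 853 and 2.91 CPM, Jun at 740 and 7.54 CPM and Hspa1a at 241 and 1.20 CPM. In sum it stood at 6761 and 207 CPM in EoP, 772 and 3570 in GMP and 1512 and 5304 in Eos. It was therefore uneven within each cell type.

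In all, 1359 genes were higher and 2453 lower in EoP than in GMP of 14324 tested, and 931 and 2335 of them by at least 2-fold. With a library left out the numbers fell to 423 higher and 312 lower without GMP replicate 1, 564 and 437 without GMP replicate 2, 639 and 704 without EoP replicate 1 and 932 and 673 without EoP replicate 2. They rose to 2346 and 3552 without Eos replicate 1 and 2322 and 3506 without Eos replicate 2. The share that was higher, 35.7%, depended on scaling and on weakly counted genes: it was 25.2% with upper quartile factors (median shift in log2 fold change −0.18), 14.3% with library size alone (−0.46), 58.4% among genes of at least 50 counts, 54.9% among genes with a promoter peak and 87.0% for RPKM. No direction of change over all genes is therefore given for this step.

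From EoP to Eos, most granule genes fell. Most genes of the eosinophil surface receptor and interferon-response lists and all neutrophil markers tested rose. Prg2 was 40.5-fold lower in Eos (log2 fold change −5.34, SE 0.83), Epx 77.3-fold (−6.27, SE 0.69) and Prg3 75.3-fold (−6.24, SE 0.55), with 2 of 2 Eos libraries below both EoP libraries (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00118, 0.000185 and 5.40e-05). Of 11 granule genes 0 rose and 10 fell, 0 and 11 over the list alone and at the lowest 4 falls with a library left out (camera adjusted p = 7.57e-07; adjusted p = 0.430 with an estimated correlation). Ear10 fell less (−2.28, SE 0.41). Retnlg, a resistin-like gene of neutrophils, rose 4051-fold to 27874 ± 10302 CPM (log2 fold change 11.98, SE 0.80), Adam19 539-fold (9.07, SE 0.62) and Pla2g7, for an enzyme that breaks down platelet-activating factor, 344-fold (8.43, SE 0.51), each in both Eos libraries (edgeR, Benjamini-Hochberg adjusted p = 1.48e-05, 1.72e-05 and 1.22e-05). Other large rises were in genes with 1 to 3 counts in EoP, given as ratios with counting intervals, namely Tmem229a 2577 (881.5 to 12500), Adamdec1 817 (146 to 32327) and Hyal5 418 (115 to 3457). Cyp11a1 fell by 6.19 (SE 0.39) and the zinc transporter gene Slc30a2 by 5.42 (SE 0.47).

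Surface receptor and adhesion genes had 18 rises and 1 fall of 26 (camera adjusted p = 5.10e-13; adjusted p = 0.283 with an estimated correlation). Beside Ccr3, Fpr1 had no count in EoP and was at least 118-fold higher in Eos, and the complement receptor genes C3ar1 and C5ar1 rose by 6.4 (SE 0.48) and 6.12 (SE 0.49). Neutrophil markers rose in the same libraries, from 2459 and 2211 to 48310 and 55491 CPM in sum, and which cells the receptor RNA came from was not measured. Of 25 lineage transcription factors 6 rose and 4 fell (camera adjusted p = 0.519). Id2 rose by 2.79 (SE 0.27), Nfia by 1.87 (SE 0.38) and Stat5b by 1.22 (SE 0.24), in both Eos libraries (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.000100, 0.00432 and 0.00350). Gata2 fell by 2.83 (SE 0.55) and Runx1 by 1.54 (SE 0.32), also in both (edgeR, Benjamini-Hochberg adjusted p = 0.00362 and 0.00476). Calls lost with a library left out were the rises of Ikzf3 (1.26, SE 0.30; adjusted p = 0.0880 without EoP replicate 1), Ikzf2 (1.14, SE 0.26; 0.0709 without EoP replicate 1) and Sfpi1 (0.88, SE 0.23; 0.132 without EoP replicate 2), and the falls of Id1 (−1.62, SE 0.42; 0.170 without EoP replicate 1) and Xbp1 (−1.26, SE 0.38; 0.131 without EoP replicate 1 and 0.0511 without Eos replicate 2). Gata1 stayed near its EoP level (0.25, adjusted p = 0.427).

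Most genes for replication, mitosis, protein folding and ribosome biogenesis fell at this step. Of 33 replication genes 0 rose and 32 fell (camera adjusted p = 2.95e-13), and of 28 mitosis genes 0 rose and 28 fell (4.52e-11). Of 26 endoplasmic reticulum folding genes 0 rose and 22 fell, 0 and 23 over the list alone (2.70e-11), and each of these lists had an adjusted p = 0.430 with an estimated correlation. Prim1 fell by 2.39 (SE 0.46), Mcm3 by 2.22 (SE 0.44), Ndc80 by 1.92 (SE 0.32), Top2a by 1.91 (SE 0.33), Creld2 by 2.60 (SE 0.33), Calr by 2.58 (SE 0.38) and Hspa5, for the chaperone BiP, by 2.5 (SE 0.46). Of 14 cell cycle inhibitors 7 rose and 3 fell (0.218), with Cdkn1b, for p27, up by 2.16 and Cdkn2c down by 2.21. Ribosome biogenesis genes had 1 rise and 25 falls of 30, 1 and 27 over the list alone (5.50e-09; adjusted p = 0.430 with an estimated correlation), with Gnl3 down by 1.99 (SE 0.33). Ribosomal protein genes had 0 rises and 38 falls of 79, 1 and 43 over the list alone (2.94e-07; adjusted p = 0.477 with an estimated correlation). Oxidative phosphorylation genes had 0 and 26 of 77, 0 and 25 over the list alone (1.42e-05; adjusted p = 0.587 with an estimated correlation). Both counts depended on libraries: ribosomal falls were 3 without EoP replicate 1, 24 without Eos replicate 2 and 48 without Eos replicate 1. Oxidative phosphorylation falls were 17 without either GMP library, 1 and 5 without EoP replicates 1 and 2, 8 without Eos replicate 2 and 47 without Eos replicate 1. Rpl10a fell by 1.71 (SE 0.27) and Atp5g3 by 1.24 (SE 0.25).

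Neutrophil markers, and most genes of the monocyte and erythroid lists, rose at this step. All 23 neutrophil markers tested rose (camera adjusted p = 1.31e-35; adjusted p = 0.120 with an estimated correlation). Ltf rose 344-fold (log2 fold change 8.43, SE 0.42, both Eos libraries; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 7.46e-06), S100a9 43.6-fold and Ngp 22.1-fold, and Stfa2l1 and Stfa2, with no count in EoP, at least 80.2-fold and 30.8-fold. Of 11 primary granule genes 7 rose and 1 fell (camera adjusted p = 0.0160; adjusted p = 0.477 with an estimated correlation). The list call was lost without GMP replicate 1, GMP replicate 2 or Eos replicate 1 (camera adjusted p = 0.0703, 0.139 and 0.171). The rises were led by Elane (3.26, SE 0.54, both Eos libraries, though these stood at 2167 and 587 CPM; edgeR, Benjamini-Hochberg adjusted p = 0.00165), Hp (3.22, SE 0.42), Prtn3 (3.16, SE 0.53) and Igsf6 (2.51, SE 0.25). Monocyte, macrophage and dendritic cell genes had 16 rises and 2 falls of 24 (camera adjusted p = 5.74e-05; adjusted p = 0.430 with an estimated correlation), with Lyz2 up 54.6-fold and C1qc by 5.79 (SE 0.86). Erythroid genes had 15 rises and 0 falls of 19, 16 and 0 over the list alone and 10 at the lowest with a library left out (1.42e-05; adjusted p = 0.430 with an estimated correlation), among them the identically counted pairs Hbb-b2 and Hbb-bt (5.13, SE 0.77) and Hba-a1 and Hba-a2 (5.03, SE 1.05). B cell genes had 7 rises and 0 falls of 15, 9 and 1 over the list alone, and 4 without EoP replicate 1, 12 without EoP replicate 2 and 2 without Eos replicate 1 (0.00780; adjusted p = 0.587 with an estimated correlation), with Pax5 up by 4.42 (SE 0.91) and Cd22 by 4.12 (SE 0.88). This list call was lost without EoP replicate 1 or Eos replicate 1 (camera adjusted p = 0.0771 and 0.0833).

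Interferon-response genes had 20 rises and 1 fall of 23 (camera adjusted p = 3.61e-10; adjusted p = 0.144 with an estimated correlation) and pattern recognition genes 18 and 1 of 26 (1.14e-06; adjusted p = 0.144 with an estimated correlation). Rsad2 rose by 5.75 (SE 0.47), Oas3 by 4.84 (SE 0.27), Tlr13 by 7.79 (SE 0.45) and Nod2 by 3.95. Cytokine and chemokine genes had 9 rises and 0 falls of 25 (0.00254; adjusted p = 0.430 with an estimated correlation), with Il1rn, for the interleukin-1 receptor antagonist, up by 6.42 (SE 0.43) and Ccl6 by 4.68 (SE 0.42). Lipid mediator genes had 8 rises and 1 fall of 12, with 4 rises at the lowest when a library was left out (0.00380; adjusted p = 0.313 with an estimated correlation). Ptges fell by 4.09 (SE 0.75). Mast cell and basophil genes had 3 rises and 7 falls of 13 (0.0161; adjusted p = 0.430 with an estimated correlation). This call was lost without GMP replicate 1, GMP replicate 2 or Eos replicate 1 (camera adjusted p = 0.0885, 0.168 and 0.250). Prss34 fell by 5.95 (SE 0.79), Mcpt8 by 5.13 (SE 0.81), and Cpa3 (−4.78, SE 0.52) and Ms4a2 (−4.28, SE 0.69) also fell. Stem and progenitor genes had 7 rises and 8 falls of 27, 7 and 10 over the list alone (0.365), with Hoxa9 down by 4.82 (SE 0.81). T and natural killer cell genes had 6 and 2 of 15 (0.111), megakaryocyte genes 2 and 2 of 11 (0.778), and stromal genes 1 and 1 of 12, 0 and 1 over the list alone (0.804). In the stress list 0 genes rose and 3 of 19 fell, 0 and 0 over the list alone (0.531); 8 rose without EoP replicate 1 and 10 fell without EoP replicate 2. Their falls rested on EoP replicate 1. Cd69 (−3.88) was −0.32 without it (adjusted p = 0.705) and lost its call in 2 fits, Hsph1 (−2.05) was −0.15 (0.849) and lost it in 4, and Ier3 (−3.35, SE 1.13) was 0.29 (0.805) and lost it in 3.

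Of the genes tested, 2733 were higher and 2540 lower in Eos than in EoP, 2223 and 2000 by at least 2-fold. Without EoP replicate 1 the numbers were 1658 and 1361, and without EoP replicate 2 they were 1794 and 1454. The median log2 fold change moved by 0.11 with DESeq2 size factors and by −0.12 with library size alone, and the share higher, 51.8%, was 25% for RPKM.

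**Figure D2:**
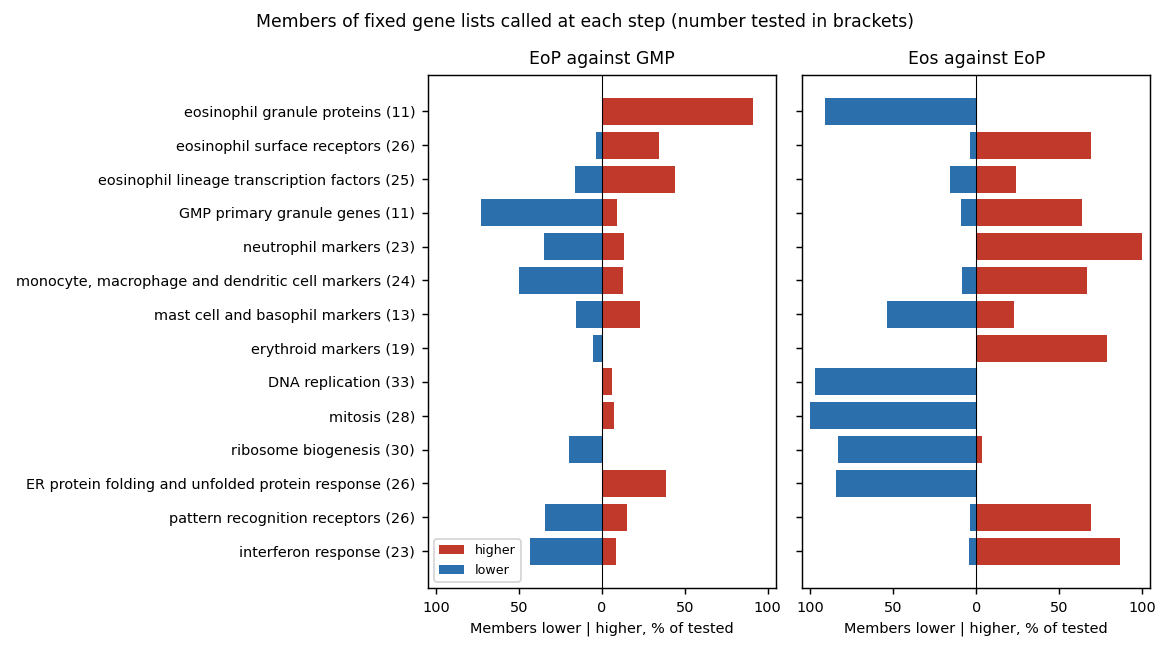
Percent of the tested members of fixed gene lists called lower (left, blue) or higher (right, red) in EoP against GMP and in Eos against EoP. The number tested is in brackets.

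Most surface receptor, eosinophil granule and neutrophil genes tested were called higher in Eos than in GMP. The camera adjusted p of these lists was 2.18e-18, 2.55e-06 and 2.33e-22, and 0.159, 0.482 and 0.145 with an estimated correlation. Serpinb2 and the homeobox gene Mkx, with no count in GMP, were at least 2305-fold and 1018-fold higher in Eos, and Retnlg rose by 13.97 (SE 0.87), Ccr3 by 11.01 (SE 0.50) and Il5ra by 8.81 (SE 0.45), in both Eos libraries (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 3.88e-06, 1.48e-06 and 2.11e-06). Gzmb (−5.55, SE 0.86), Apba1 (−4.87, SE 0.56) and Prss34 (−4.81, SE 0.75) fell, in both (edgeR, Benjamini-Hochberg adjusted p = 0.000752, 0.000124 and 0.000764). Cd34 (−3.27, SE 0.36) and Kit (−2.01, SE 0.40) also fell, in both Eos libraries (edgeR, Benjamini-Hochberg adjusted p = 0.000106 and 0.00301). Granule genes had 9 rises and 0 falls of 11 and neutrophil markers 21 and 0 of 23, while Mpo was lower (−2.02, SE 0.52). Surface receptor genes had 21 rises and 2 falls of 26, stem and progenitor genes 4 and 19 of 27, replication genes 0 and 30 of 33 and ribosome biogenesis genes 0 and 28 of 30. The 19 falls of stem and progenitor genes were 13 without GMP replicate 1 and 11 without GMP replicate 2, and the 2 falls of receptor genes were 0 or 1 with any library left out. In all 3253 genes were higher and 4557 lower, 1993 lower without GMP replicate 1 and 1656 without GMP replicate 2. The share higher was 41.7%, and 23.0% with library size alone (median shift −0.58, and −0.23 with upper quartile factors).

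Genes called at both steps were grouped by the direction of each. Highest in EoP were 297 genes, led by Epx, Prg3, Prg2, Lipg (log2 fold changes 7.32 from GMP and −5.24 to Eos), P2rx3 (5.27 and −3.88) and Slc30a2 (3.81 and −5.42). Rising at both steps were 514 genes, among them Ccr3 (4.46 and 6.55), Ccl6 (4.97 and 4.68), Cyp4f18, which inactivates leukotriene B4 (4.40 and 4.52), and Pla2g3 (4.05 and 4.79). Also rising were Serpinb2 and Mkx, at least 72.6-fold and 57.2-fold higher in EoP than in GMP and then 4.94 and 4.18 log2 units higher in Eos. Lowest in EoP were 516 genes, among them Prom1 (−5.55 and 4.68), Tshr (−5.04 and 4.54), Ugt8a (−4.46 and 4.32), the complement gene C3 (−4.39 and 4.24), and Lrg1 and Sel1l3, each with 2 counts in EoP. The ratio of EoP to GMP was 0.0136 (0.00163 to 0.0505) for Lrg1 and 0.0551 (0.00635 to 0.219) for Sel1l3, whose call was lost without EoP replicate 2 (adjusted p = 0.0624). The ratios of Eos to EoP were 231 (63.5 to 1911) and 298 (82.0 to 2464). Falling at both steps were 52 genes, among them Bmyc (−2.31 and −2.14), Bex6 (−2.34 and −2.09), Armcx4 (−2.49 and −1.75), Sestd1 (−1.64 and −1.51), Fam189b (−1.35 and −1.83) and Bzw2 (−1.62 and −1.32), each of which lost a call with some library left out. Without GMP replicate 1 the numbers were 107 highest, 150 lowest, 176 rising and 1 falling, and without Eos replicate 1 they were 573, 619, 947 and 379. If the calls of the steps were independent 241, 468, 259 and 435 genes would fall in these groups. Simulations in which no gene was changed gave means of 0.1, 0.15, 0 and 0. With so few calls the adjusted threshold was stricter there than in the data. These means therefore cannot bound the number of genes that noise adds here. Noise in the shared EoP libraries enters the steps with opposite signs, so part of the excess of genes highest or lowest in EoP may come from the shared libraries.

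H3K4me3 peaks in EoP were mostly shared with the other cell types. The authors listed 30645 peaks in GMP, 19816 in EoP and 33847 in Eos, with median lengths of 343, 405 and 190 bases, of which 65.6%, 77.1% and 46.3% were annotated to promoters. Of the EoP peaks 93.6% overlapped a GMP peak and 85.7% an Eos peak, whereas 56.7% of GMP peaks and 47.4% of Eos peaks overlapped an EoP peak. The lists reached down to a −log10 q of 0.701 in GMP, 0.705 in EoP and 0.705 in Eos. The median pileup was 16, 17 and 6. In Eos 23.4% of the peaks were intergenic, at a median pileup of 2. The promoter share and overlap of the Eos list therefore include many weak peaks and do not measure chromatin differences alone. Of 23471 genes, 11005 had a promoter peak in all 3 cell types, 1399 in GMP only, 591 in GMP and Eos, 283 in GMP and EoP, 262 in Eos only, 19 in EoP only and 18 in EoP and Eos. With the 19816 top-ranked peaks of each list these numbers were 10719, 829, 215, 426, 178, 71 and 109, so the sets depended on the lengths of the lists. Gata1, Ikzf3, Id2, Cebpe, Alox15, Kit, Cd34, Siglec5, Prg2 and Epx had a promoter peak in all 3, and Irf8, Csf3r and Gata2 in GMP and Eos. Il5ra had a peak in EoP (chromosome 6, 106747898 to 106748042) and Eos but not in GMP, and Ear1 (chromosome 14, 43818676 to 43818869) and the shared promoter of Ear2, Ear3 and Ear12 (chromosome 14, 44102648 to 44102966) likewise. Ccr3 had a peak in Eos only (chromosome 9, 124022752 to 124023268), as did Retnlg (chromosome 16, 48872982 to 48873180) and Mmp9, although Ccr3 RNA was already called higher in EoP. Elane (chromosome 10, 79886645 to 79887292) and Prtn3 (chromosome 10, 79879969 to 79882707) had a peak in GMP only, Mpo (chromosome 11, 87794510 to 87795559) and Prg3 in GMP and EoP, and Ltf and S100a9 in none. Each cell type had 1 library of unknown depth, so there is no replicate check or test of these differences.

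Genes with a promoter peak had more RNA. The median RPKM with and without a peak was 2.23 and 0.0874 in GMP, 4.03 and 0 in EoP and 2.38 and 0.0082 in Eos. Of genes at 1 RPKM or more 95.6% had a peak in GMP, 93.3% in EoP and 93.0% in Eos. The Spearman correlation of RPKM with summed peak length over genes with a peak was 0.502 in GMP, 0.408 in EoP and 0.491 in Eos, and with fold enrichment 0.291, 0.204 and 0.242; genes are not independent replicates.

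Promoter peaks listed in only 1 of a pair of cell types went with RNA change in 5 of 6 sets. Of 27 tested genes with a peak in EoP and not GMP 11 rose and 1 fell (camera adjusted p = 8.37e-13; adjusted p = 0.0229 with an estimated correlation). With the top-ranked peaks of each list 45 rose and 20 fell of 137 (median log2 fold change 0.34, against 0.86). Among the 11 were Cybb (chromosome X, 9468990 to 9469214), Ear2, Ear3 and Ear12. Of 1082 with a peak in GMP and not EoP 35 rose and 481 fell (6.26e-15; adjusted p = 0.00154 with an estimated correlation). These falls were 89 without GMP replicate 1, 110 without GMP replicate 2, 178 without EoP replicate 1 and 168 without EoP replicate 2. Of all 2453 genes lower in EoP 1790 were under 10 CPM in every cell type, so many of these falls need not follow the peak. At 10 CPM or more, a setting added after seeing the data, 23 rose and 80 fell of 261 (median log2 fold change −0.47, against −2.17). Of its named genes Scamp5 (chromosome 9, 57467538 to 57468063) fell by 4.58 (SE 0.73). The calls of Pros1 (−1.76), Tmem178 (−3.79) and Pcp4l1 (−2.16) were lost in 4, 4 and 3 fits with a library left out. Their log2 fold changes in those fits were −1.30 to −1.94, −3.04 to −4.12 and −1.27 to −2.33. Of 524 genes with a peak in Eos and not EoP 183 rose and 32 fell (4.21e-10; adjusted p = 0.0229 with an estimated correlation). The named rises were Bank1 (4.27; chromosome 3, 136325480 to 136326028), Tgm2 (6.61), Adam19 (9.07) and Osgin1 (4.17). Of 212 with a peak in EoP and not Eos 27 rose and 32 fell (0.262), the falls with Car9 (−2.02; chromosome 4, 43507962 to 43508918), Nme4 (−2.09; lost without EoP replicate 2, adjusted p = 0.0646), Slc17a9 (−1.24; lost without EoP replicate 1 or 2, 0.0632 and 0.0768) and Slc22a3 (−2.47). Of 163 with a peak in Eos and not GMP 93 rose and 24 fell (1.31e-19; adjusted p = 0.0419 with an estimated correlation), the falls being 5 without GMP replicate 1, 6 without GMP replicate 2 and 14 without Eos replicate 2. Padi4 rose by 7.14 (chromosome 4, 140773712 to 140774203), Il1rn by 7.41, Bank1 by 6.26 and Ptafr, for the receptor of platelet-activating factor, by 4.98 (chromosome 4, 132564189 to 132565081). Of 906 with a peak in GMP and not Eos 64 rose and 409 fell, 129 without GMP replicate 1 and 125 without GMP replicate 2 (2.97e-06; adjusted p = 0.0236 with an estimated correlation), and at 10 CPM or more 44 rose and 100 fell of 207. Its named genes were Gspt2 (−4.52), AI450353 (−2.27), Fam188b, which had no count in Eos and was at least 23.1-fold lower, and Gm14420, with 1 count in Eos (ratio 0.0368, 0.000891 to 0.228; lost in 3 fits, adjusted p from 0.0614 to 0.0991).

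**Figure D3:**
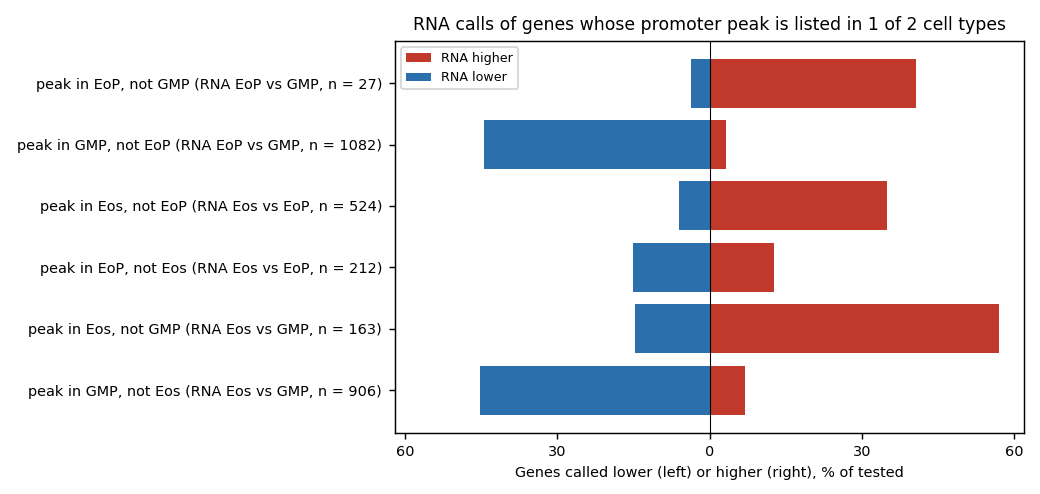
Percent of tested genes called lower (left, blue) or higher (right, red) in RNA, for genes whose promoter peak was listed in 1 cell type of a pair and not in the other. Bars are the 6 sets, with the number tested in brackets.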

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

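The settings of at least 10 CPM in a cell type, of genes with a promoter peak, and without Rn45s and Prg2, and the recalculated correlations of RPKM with peak length, were chosen after seeing the data. Without Rn45s and Prg2 no count of calls moved by over 1.5 times. Over all alternatives, the values of named genes kept their direction and side of the threshold in 8291 cases, lost a call in 671, gained one in 32 and turned direction in 1. Ier3 in Eos against EoP was 0.29 log2 without EoP replicate 1, against −3.35, and −4.27 without EoP replicate 2. For gene lists the numbers were 1463, 104, 47 and 0. Of the lost list calls 56 came with the estimated correlation. In EoP against GMP, mitosis genes lost theirs with at least 50 counts (camera adjusted p = 0.125) and at 10 CPM or more (0.162), anti-apoptotic genes with these (0.163 and 0.108) and among genes with a promoter peak (0.0695), histone genes in the same settings (0.259, 0.224 and 0.258), stem and progenitor genes with no filter (0.114), and interferon-response genes with no filter (0.288). In Eos against EoP, mast cell and basophil genes lost it with no filter (0.138), at 10 CPM or more (0.0563) and among genes with a promoter peak (0.0963), B cell genes at 10 CPM or more (0.226), and erythroid genes among genes with a promoter peak (0.571). In Eos against GMP, B cell genes lost it with at least 50 counts (0.154) and at 10 CPM or more (0.297), stem and progenitor genes with no filter (0.0625) and among genes with a promoter peak (0.0686), erythroid genes among the latter (0.864), cytokine genes with no filter (0.107) and at 10 CPM or more (0.0602), lysosome genes at 10 CPM or more (0.0705), and histone genes with library size alone (0.0617).

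Leaving out a library moved many counts, and the lone library of a cell type was then assumed to vary like the others. Genes higher in EoP than GMP ran from 423 to 2346 and lower from 312 to 3552; higher in Eos than EoP from 1658 to 3114 and lower from 1361 to 3283; and lower in Eos than GMP from 1656 to 4515. Highest in EoP ran from 107 to 573, lowest from 150 to 619, rising at both steps from 176 to 947 and falling at both from 1 to 379. Lists called ran from 13 to 16, 17 to 23 and 21 to 24. The correlation of RPKM with peak length ran from 0.495 to 0.502 in GMP, was 0.406 to 0.407 in EoP and ran from 0.481 to 0.497 in Eos. Each of these fits had fewer samples, and why several counts rose without an Eos library was not tested.

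With library size alone 602 genes were higher in EoP than GMP, 2019 higher in Eos than GMP, 143 highest in EoP, 243 rising and 220 falling at both steps. Falling at both steps were 111 with upper quartile factors and 85 with limma-voom; with no filter they were 138, and 457 were highest in EoP. With at least 50 counts, which tests fewer genes, 899 were higher and 640 lower in EoP than GMP, 2972 lower in Eos than GMP, 276 lowest in EoP and 33 falling. At 10 CPM or more, also fewer genes, 861 were higher and 583 lower in EoP than GMP, 2844 lower in Eos than GMP, 194 highest and 244 lowest in EoP and 33 falling. Among genes with a promoter peak 1055 were lower in EoP than GMP, 316 lowest in EoP and 25 falling. On RPKM 2363 were higher and 352 lower in EoP than GMP, 1440 higher and 4311 lower in Eos than EoP, 834 highest and 102 lowest in EoP and 32 falling. At 2-fold or more 195 were highest, 316 rising and 31 falling. With an estimated correlation 0 lists were called for EoP against GMP, 0 for Eos against EoP and 0 for Eos against GMP. Genes with a peak in EoP and not Eos had a p, not adjusted over the sets, of 0.000276 with stricter significance, against 0.262, and between 0.102 and 0.835 otherwise. Where no construction is named the cause was not tested. The other peak sets stayed on their side of the threshold with the same direction in all 14 settings each, but their size moved. With top-ranked peaks, genes with a peak in EoP and not GMP had 45 rises and 20 falls of 137, against 11 and 1 of 27. With stricter significance, genes with a peak in GMP and not EoP had 151 rises and 415 falls of 1857 (median log2 fold change −0.45, against −2.17), and with a peak in Eos and not EoP 258 and 176 of 908 (0.19, against 1.18).

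The replicate numbers did not pair the samples: deviations of libraries with the same number correlated at −0.0995, 0.0194 and −0.0849 between cell types, and with the number as a replicate block 1508 genes were lower in EoP than GMP, against 2453. The block also ended the list calls of interferon-response genes in EoP against GMP (camera adjusted p = 0.0620), primary granule and mast cell and basophil genes in Eos against EoP (0.112 and 0.168) and cytokine genes in Eos against GMP (0.172). Other RPKM offsets were not run, since counts were at hand. With 2 libraries per cell type, few of the simulated changes of 2-fold were found. Few genes were changed in that simulation, which can make the adjusted threshold stricter than in the data, so this need not hold here. Of 2733 genes called higher and 2540 called lower in Eos than in EoP, 2223 and 2000 changed by at least 2-fold.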

Other observations

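The tests for reads spread by length and for peaks at Y-linked genes were set before their results were seen, and the other 7 tests were chosen only after the result was seen.

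Of the lists for cell death, metabolism and chromatin, camera called anti-apoptotic genes and histone genes in EoP against GMP (adjusted p = 0.0232 and 0.0332; 0.509 and 0.863 with an estimated correlation) and histone genes and transcription factor families in Eos against EoP (2.95e-07 and 0.0284; 0.477 and 0.430). The first histone call was lost without GMP replicate 2 or EoP replicate 1 (0.158 and 0.468), and the transcription factor call without EoP replicate 2 (0.0889). Anti-apoptotic genes had 3 rises and 0 falls of 13 from GMP to EoP, with Bcl2a1b up by 5.58 (SE 0.64), and 2 and 3 from EoP to Eos, with Birc3 up by 2.73 (SE 0.31) and Bcl2 at −2.5 (SE 0.44). Pro-apoptotic genes had 2 and 3 of 14, then 5 and 1 (3 and 2 rises without EoP replicates 1 and 2), with Fas up by 3.05. Glycolysis and glucose transport genes had 3 and 3 of 23, then 8 and 3 (5 rises without EoP replicate 2), led by Slc2a3 (3.91, SE 0.27). Lysosome and autophagy genes had 6 and 2 of 30, then 11 and 3, and the first rises ran from 2 to 9 with a library left out. Ctsh rose by 4.34 (SE 0.33) and Cd63, a granule membrane gene, by 2.95 (SE 0.29) in EoP, and Cd63 was lower in Eos (−2.06). Enzymes of H3K4 methylation had 1 and 0 of 21, then 8 and 2 (3 rises without EoP replicate 1 and 4 without EoP replicate 2), with Kmt2c up by 1.62 and Dpy30 at −1.30. Transcription factors of large families had 31 and 39 of 235, then 72 and 24, with Relb up by 4.92; with a library left out the first step ran from 10 to 52 rises and from 6 to 58 falls, and the rises of the second were 47 and 46 without EoP replicates 1 and 2. Histone genes had 4 and 0 of 42, then 0 and 18, with Hist1h1b at −3.00 (SE 0.44); the rises of the first step ran from 1 to 10 and the falls of the second from 11 to 30 with a library left out. Housekeeping genes had 1 and 0 of 12, then 2 and 2, with Hprt at −1.25.

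In GMP, many genes with no promoter peak in any cell type held low counts. Of 9894 such genes 67.1% and 74.0% had a count in the GMP libraries, against 23.7% and 28.4% in EoP and 36.4% and 41.9% in Eos, and olfactory and vomeronasal receptor genes held 631 and 673 counts per 1e6 in GMP against 11.1, 21.6, 35.8 and 65.6. Greater depth was excluded, since the highest GMP total, 6.58 M, was below all others, and so was transcription of the receptor genes from marked promoters, since 0.368% of the 543 with a count in both GMP libraries had a GMP peak. Reads spread over transcripts by their length stay open as the source. The count correlated with length at a Spearman rho of 0.477 and 0.543 in GMP, against 0.214 to 0.323 in the others. Lengths were ratios of count to RPKM, known for 8419 of these genes with a count somewhere, so they were not independent of the counts. The larger share of genes without a count in EoP and Eos can also lower rho there. The test therefore cannot decide this. Whether such reads came from genomic DNA was not tested.

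In Eos, neutrophil and primary granule genes were high. GMP-like cells were excluded as the source of the neutrophil markers, since 21 of 23 were called higher in Eos than in GMP (edgeR), by up to 13.97 log2 (Retnlg). As the source of the primary granule genes GMP-like cells stay open. The 8 primary granule genes called lower in EoP than in GMP stood at medians of 38.4% and 12.7% of GMP in the Eos libraries. Beside them 21 other GMP genes stood at 40.8% and 22.7%. These 21 were chosen as abundant in GMP, called lower in EoP and at a small share of GMP there. Of 1439 genes of at least 100 CPM in GMP, 7 stood under 0.5 times the primary granule medians (Prss34, Gria3, Cpa3, Mcpt8, Irf8, Il6st and Cd34). The bound for that count was set after it was seen. A neutrophil population of fixed makeup stays open too. The log2 ratios of 21 markers, Eos replicate 1 to 2, had an interquartile range of 0.657, beside 0.701 for 8481 other genes. They ran from −0.772 (Retnlg) to 1.69 (Fcnb), with a median of 0.323. The ends of the range were not taken for the other genes, so these values cannot decide it. Neutrophil-lineage cells of several stages and transcription in eosinophils cannot be told apart without a neutrophil sample. In Eos 11 neutrophil markers had a promoter peak, against 3 in GMP and 3 in EoP.

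Y-linked genes were at the floor in GMP RNA. Of Eif2s3y, Ddx3y, Uty and Kdm5d, 0 had over 3 counts over the GMP libraries. This test restates the pattern, so GMP pools without male mice stay open as its source. Xist, at 41833 and 21695 counts in GMP, 12758 and 44289 in EoP and 15449 and 16158 in Eos, shows female cells in every pool. Erdr1, with 67 and 157 counts in GMP, was left out as pseudoautosomal after those counts were seen, and would have turned the test. Silence of Y-linked genes in GMP as a cell type stays open: 4 of these 4 genes had a GMP promoter peak, which had been set to exclude it, but in a count made after that result 544 of 13278 genes with a GMP promoter peak had at most 3 counts over the GMP libraries. In Eos these genes had RNA counts and 0 had a promoter peak, and whether RNA and H3K4me3 came from the same sorts, or from mice of which sex, was not given. Any difference in the sex of the pools cannot be told apart from cell type in the RNA comparisons with GMP.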
